A study of Bacillus subtilis subsp. subtilis NCIB 3610 = ATCC 6051 = DSM 10 with 4 samples.

How the data were processed

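Genomic DNA of an undomesticated strain of Bacillus subtilis was sequenced from 4 samples, 1 per genotype as labelled: wild type, a deletion of rnhP and rnhC, a deletion of ppsA-E, and a deletion of all of these. Per the labels, DNA was extracted with a kit for Gram-positive bacteria and sequenced at a core facility. Per the file headers, the deposited signal of each sample is read depth, also called coverage, at every position of 1 sequence, in 3 numbered columns and a further column for their average. The average equalled the mean of the 3 columns to within 2.84e-14 at every position and was not used further. The submitters' processing notes name Bowtie2 2.3.5.1, SAMtools 1.10, Picard 2.23.0 and bedtools 2.29.1, with no role or order. The genome build, the read filters, the treatment of duplicate and repeat reads, and the scaling are not given in the sources used here. The depth values were whole numbers that differed in total between columns, so they were taken as not normalized.

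No source used here says whether the 3 columns of a sample are cultures, libraries or sequencing runs. Errors are therefore given as the SD over 3 depth columns, and every p-value measures only the spread between columns, which may be technical. Between columns of 1 sample, the variance of the depth ratio over windows was 13.1 to 657 times that of counting noise, over 12 pairs of columns, so no 2 columns agreed within sampling noise and none was merged.

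The number of reads was estimated as the depth sum divided by a read length of 38 bp, the length of 8 of 8 isolated stretches of depth inside the emptied intervals. This gave 49752371 to 76865959 reads per column and a counting error of 0.234% to 0.291% for a window of 10 kb at the mean depth. Reads without molecular identifiers are not independent molecules, so this covers counting error only.

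Depth was divided by the median depth of the chromosome in the same column (relative depth). Windows of 10 kb and bins of 1 kb were averaged. Of 421 windows, 5 overlapped a targeted interval and were counted apart, which left 416. Targeted intervals were found as stretches under 0.05 of the median depth in the sample labelled with all deletions and covered in the wild type. Stretches under 0.02 in all samples gave 7 gaps, which matched in number and order the 7 clusters of rRNA operons in a gene table of assembly GCF_006088795.1 (ASM608879v1). Positions in that table differed from the deposited positions by up to 409 bp at the first 6 gaps and by at least 4785 bp at rnhC, so the table served only for gene names and gene order, and all coordinates are positions in the deposited files.

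Rules fixed before the data were examined were the relative depth of the targeted loci, the origin to terminus ratio, the count of windows past a log2 ratio of 0.3 in 6 contrasts, local regions of 3 or more bins past 0.5 after subtraction of a running median over 100 bins either side, the difference of differences, and the correlation of contrasts across windows. These have no test, because each genotype is 1 sample. The origin window was 50 kb either side of the first position, where dnaA stands first in the gene table. The terminus window was 50 kb either side of the midpoint, the alternative fixed for the case that rtp could not be placed, and so the planned comparison of midpoint and rtp was void. Plasmid sequence was not analysed here, so neither rnhP, a plasmid gene, nor the plasmid to chromosome ratio is reported.

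The rule for named genes (per contrast the 8 highest and 8 lowest genes, at most 2 from any 20 kb) could not be run without gene positions in this build. It was applied to 10 kb windows instead. Gene lists were assigned by gene order to 7 segments bounded by the rRNA gaps and both targeted intervals, and a list is described through its segment. The SD of a segment's log2 ratio is over the columns of the sample in the numerator. It leaves out the spread of the reference sample. Prophages could not be placed within a segment, so they were not removed from any window, and the strand of genes was not analysed.

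After the columns had been seen, 5 analyses were added. A linear model over the 12 columns was fitted with limma 3.58.1 in R 4.3.3 to log2 relative depth, all 4 samples sharing 1 estimate of the spread, with Benjamini-Hochberg adjustment over 416 windows and a threshold of 0.05. Exact two-sided permutation tests of 3 against 3 columns were run on the origin to terminus ratio, on both arm slopes and on the difference between arms. The other additions were mean depth in blocks beside the ppsA-E interval, steps in the log2 ratio between medians of the 20 nearest bins on either side, and leaving out each column in turn or the edge peaks of 1 column. Tested on simulated data made from the wild-type columns (416 windows, 3 against 3), the linear model recovered 12 of 20 windows changed by 0.05 on the log2 scale, 20 of 20 changed by 0.1 and 20 of 20 changed by 0.3, and called 2 of 356 unchanged windows. The simulated noise was drawn independently for each window. Real columns of a sample also differed in slope along the arms, which shifts many windows together. These rates therefore need not hold for the real columns. Alternatives covered the scale, the window and bin size, thresholds, summaries, filters and removal of the trend. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.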

Results

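Read depth along the chromosome was measured in 4 Bacillus subtilis samples to ask how loss of RNase H affects chromosome coverage with and without the ppsA-E genes. RNase H enzymes remove RNA paired with DNA. The gene rnhC encodes RNase HIII, rnhP encodes an RNase H carried on the plasmid of this strain, and ppsA-E encode the plipastatin synthetase, a nonribosomal peptide synthetase. Each genotype was 1 sample with 3 depth columns of 4215607 positions. The median depth of a column was 418 to 663 reads and the mean 448 to 693. There is no replicate check by sample, and errors are the SD over 3 depth columns.

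The deleted loci were examined first. Reads were missing over 2 chromosomal intervals, and in both single-deletion samples the missing locus went against the label. The ppsA-E interval (positions 1960230 to 1997990, 37761 bp) had a relative depth of 0.480 ± 0.0086 (SD, n = 3 columns) in the wild type, where 1 is the chromosome median, and 0.604 ± 0.011 in the sample labelled ppsA-E deletion. It was empty in the library labelled rnhP rnhC deletion, with a relative depth of 1.70e-05 from 32 reads, and in the library labelled rnhP rnhC ppsA-E deletion, with 6.16e-06 from 8 reads. The rnhC interval (positions 2926051 to 2926985, 935 bp, against 942 bp for rnhC in the gene table) had a relative depth of 0.907 ± 0.012 in the wild type and 0.906 ± 0.013 in the library labelled rnhP rnhC deletion. It was empty in the library labelled ppsA-E deletion, at 0.000402 from 15 reads, and in that labelled rnhP rnhC ppsA-E deletion, at 0.000197 from 7 reads. The wild type and the sample labelled rnhP rnhC ppsA-E deletion defined the intervals, so only the single-deletion samples could disagree with their label. Of the 4 samples, these 2 did so at both loci. For this reason the samples are named by label throughout, and a direction drawn from either single-deletion sample belongs to a library whose label disagrees with its missing locus. Comparing the wild type with the sample labelled rnhP rnhC ppsA-E deletion does not depend on which single-deletion sample is which.

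Depth fell from the origin to the terminus on both arms in every sample. The origin to terminus ratio was 3.69 ± 0.079 (SD, n = 3 columns) in the wild type, 3.31 ± 0.091 in the library labelled ppsA-E deletion, 3.39 ± 0.17 in that labelled rnhP rnhC ppsA-E deletion and 3.37 ± 0.37 in that labelled rnhP rnhC deletion. In the last of these, columns 1 and 2 gave 3.50 and 3.66 and column 3 gave 2.96. With the 50 kb beyond ppsA as the terminus the ratios in the same order were 3.73, 3.02, 3.09 and 3.27 (all columns), a wider gap between the wild type and the others. That window was chosen after the data were seen. It includes the stretch beside ppsA where depth was higher than in the wild type (described below). The wider gap is therefore not separate evidence of a changed ratio. With the midpoint as the terminus, the columns of the libraries labelled ppsA-E deletion and rnhP rnhC ppsA-E deletion did not overlap those of the wild type (exact two-sided permutation test, p = 0.1 for each, the smallest p that 3 against 3 can give). Over the 24 comparisons of this family (6 contrasts, 4 measures) the smallest adjusted p of the permutation tests was 0.24, and 10 comparisons had no overlap. Chance gives no overlap in 10% of single comparisons. The 24 share columns and are not independent, so their count cannot be set against that rate.

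The arms differed between samples in balance. Right-arm minus left-arm log2 depth, taken between windows at equal distance from the origin, was −0.05 ± 0.0023 in the wild type and −0.03 ± 0.035 in the library labelled rnhP rnhC deletion. It was 0.14 ± 0.0046 in the library labelled ppsA-E deletion, a 1.1-fold higher right arm, and 0.12 ± 0.011 in the library labelled rnhP rnhC ppsA-E deletion, a 1.09-fold higher right arm. All 3 columns of each of these libraries lay above all columns of the wild type and of the library labelled rnhP rnhC deletion (exact permutation test, p = 0.1 for each; adjusted p = 0.24).

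**Figure D1:**
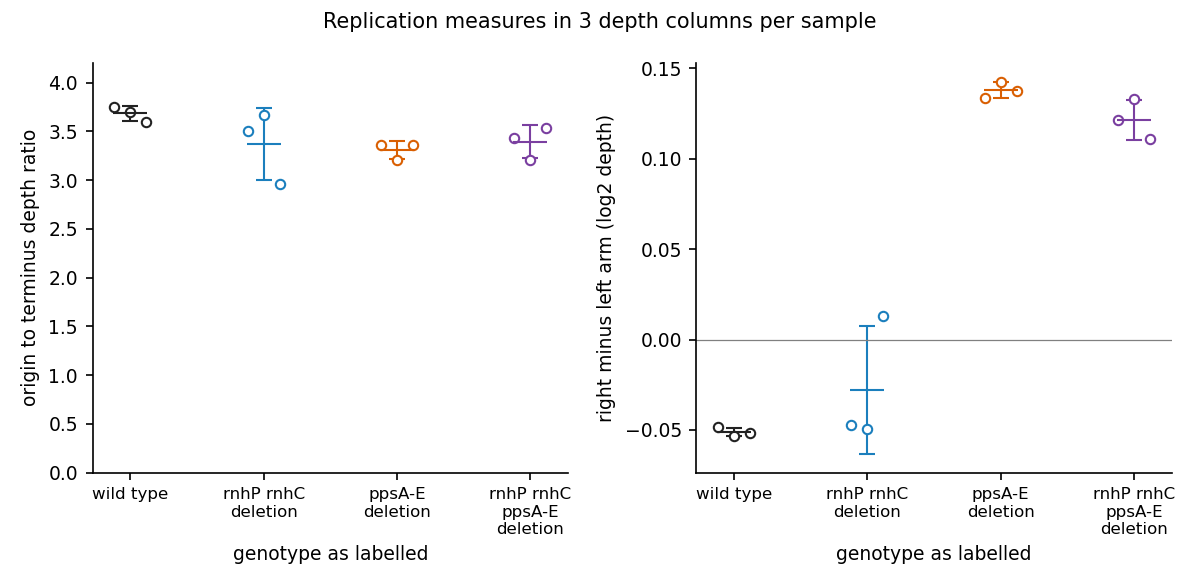
Origin to terminus depth ratio (left) and right minus left arm depth on the log2 scale (right) for the 4 samples as labelled. Circles are the 3 depth columns, the horizontal bar is their mean and the error bar the SD; column 3 of the sample labelled rnhP rnhC deletion, at 2.96 and 0.01, lies apart from its columns 1 and 2.

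The sample labelled ppsA-E deletion, which lacked rnhC reads, was compared with the wild type. Depth was higher over the right arm from the fifth rRNA gap on and around the ppsA-E interval, and lower over most of the left arm and near the origin. The segment from the sixth rRNA gap to the ppsA-E interval (positions 950914 to 1960229) had a median log2 ratio of 0.11 ± 0.0054 (SD, n = 3 columns), with 100 of 100 windows above 0. By gene order this segment holds all 29 listed genes of the defective prophage PBSX and 32 of 44 flagellar and chemotaxis genes. The segment between the fifth and sixth rRNA gaps gave 0.12 ± 0.011. The segment from the seventh rRNA gap to the end (positions 3177627 to 4215607) gave −0.13 ± 0.0078, with 103 of 103 windows below 0. It holds 11 flagellar and chemotaxis genes and 12 of the 29 other nonribosomal peptide and polyketide synthetase genes. Of the same 29 genes, 13 lie in the segment with the PBSX genes, where depth was higher, and 4 between the rRNA gaps 4 and 5. The synthetase genes as a list thus did not go with lower depth. Near the origin, the segment up to the fourth rRNA gap, which holds 35 of 58 ribosomal protein genes, gave −0.11 ± 0.034. The percentile among 10000 circular shifts was 100 for the PBSX segment and 0.85 for the last segment, but 86.3 for the segment between the fifth and sixth gaps and 28.0 for that near the origin. By limma over the 12 depth columns, 135 windows were higher and 185 lower at adjusted p under 0.05, and 152 higher and 151 lower with the mean depth as the scale. With the 0.3 threshold, 1 window was past it (2 with the mean depth and 31 with the origin window as the scale), positions 1950001 to 1960000 at 0.30, but that window was not called (limma adjusted p = 0.228), and without column 3 of the library labelled rnhP rnhC deletion, which widens the shared spread there, 352 windows were called and this window among them. The window at 1330001 to 1340000, at 0.20, was called with adjusted p = 5.03e-06 (limma).

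The highest ratio among the windows of this contrast lay beside the ppsA-E interval. Depth in the library labelled ppsA-E deletion was 1.26-fold that of the wild type inside the interval (log2 0.33, SE 0.021), 1.20-fold in the 50 kb on the ppsE side (log2 0.26, SE 0.015) and 1.22-fold in the 15 kb on the ppsA side (log2 0.29, SE 0.014). It was 1.03-fold from 30 to 80 kb on the ppsA side (log2 0.04, SE 0.013). On the ppsE side depth was still 1.13-fold from 50 to 100 kb (log2 0.18, SE 0.013) and 1.14-fold from 100 to 150 kb (log2 0.19, SE 0.016). In gene order the ppsE side holds galU, xynC, xynD, the endoglucanase gene eglS, and parC and parE, the subunits of topoisomerase IV. On the ppsA side, rtp, the replication terminator protein gene, is the 16th gene beyond ppsA and could not be placed in the deposited positions.

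**Figure D2:**
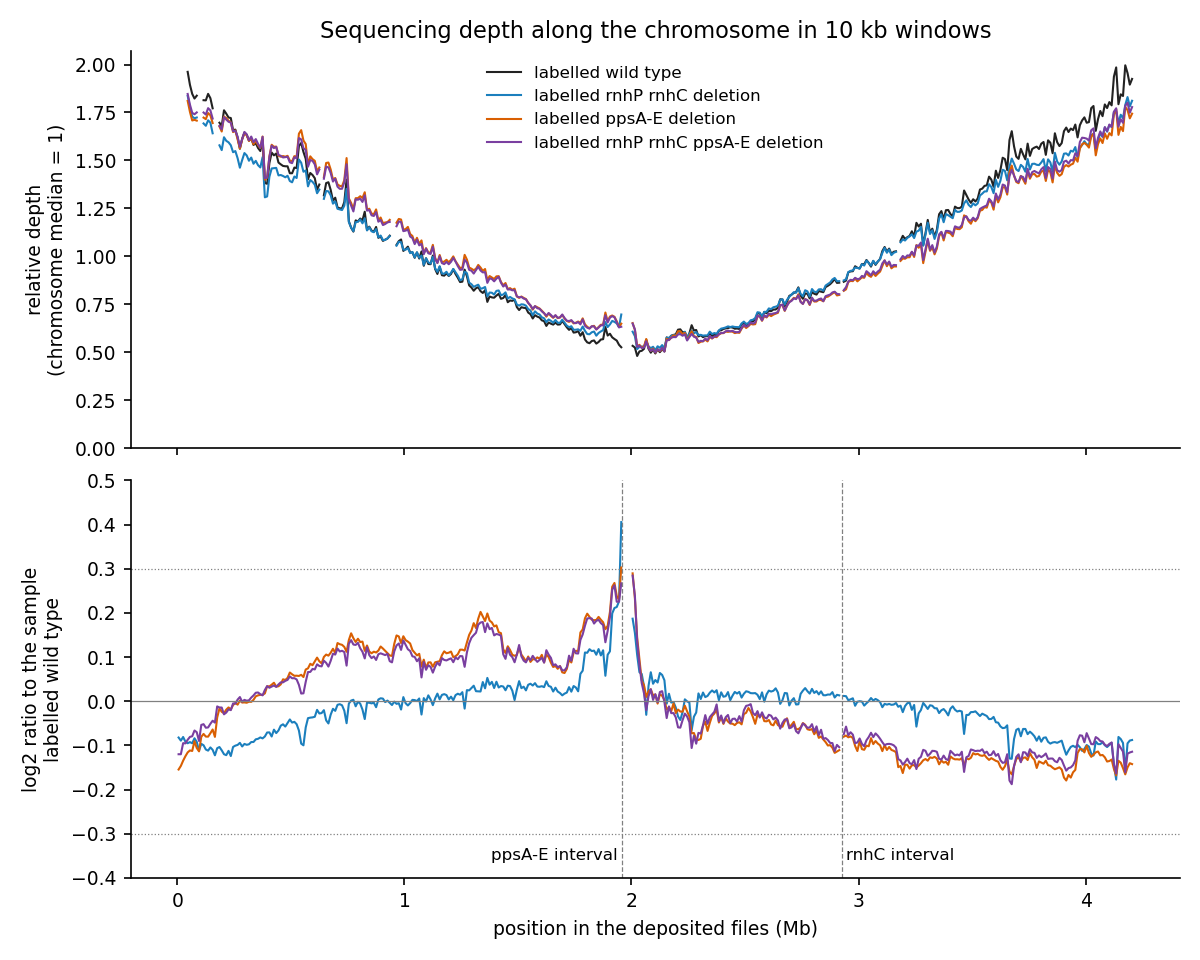
Relative depth in 10 kb windows for the 4 samples as labelled (top) and log2 ratio to the wild type for the other samples (bottom) against position in Mb; targeted windows are left out of both panels and windows at rRNA gaps of the top one, dotted lines mark the threshold of 0.3 and dashed lines both targeted intervals. The samples labelled ppsA-E deletion and rnhP rnhC ppsA-E deletion run together, above 0 over most of the right arm and below 0 over most of the left arm.

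The wild type was also compared with the library labelled rnhP rnhC ppsA-E deletion, the contrast that does not depend on the conflicting labels. The segment between the sixth rRNA gap and the ppsA-E interval, with the PBSX and most flagellar genes, was at 0.11 ± 0.0098 (100 of 100 windows above 0), and the last segment at −0.12 ± 0.025 (103 of 103 below 0). Depth was 1.19-fold higher in the 50 kb on the ppsE side (log2 0.25, SE 0.014) and 1.21-fold higher in the 15 kb on the ppsA side (log2 0.28, SE 0.015), and 1.02-fold from 30 to 80 kb beyond (log2 0.03, SE 0.019). On the ppsE side depth was 1.12-fold from 50 to 100 kb (log2 0.17, SE 0.015) and 1.14-fold from 100 to 150 kb (log2 0.18, SE 0.013). With limma, 128 windows were higher and 166 lower at adjusted p under 0.05. With the mean depth of the chromosome as the scale the split was 150 higher and 125 lower. No window was past 0.3 outside the targeted intervals, with a range of −0.19 to 0.28, but 1 was with the mean depth and 10 were with the origin window as the scale.

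The sample labelled rnhP rnhC deletion, which lacked ppsA-E reads and kept rnhC, was compared with the wild type. The last segment was at −0.07 ± 0.051 (SD, n = 3 columns), with 103 of 103 windows below 0, and the segments from the start to the fifth rRNA gap at −0.10 ± 0.068 (17 of 17 below 0) and −0.08 ± 0.062 (45 of 45). The PBSX segment was at 0.03 ± 0.039, with 90 of 100 windows above 0. Percentiles among 10000 circular shifts were 23.3 for the last segment, 11.8 and 20.5 for those near the origin and 86.5 for the PBSX segment. Without column 3 the last segment was at −0.05 (2 of 103 windows above 0), the segments near the origin at −0.07 and −0.06, and the PBSX segment at 0.00 (48 of 100 above 0). The lower values came mainly from column 1, with −0.09 in the last segment and −0.10 and −0.12 near the origin. Column 2 was at −0.01, −0.03 and −0.01 there. In columns 1 and 2 the 50 kb on the ppsE side had a relative depth of 0.544, against 0.554 in the wild type (log2 −0.03), and 0.528 against 0.531 in the 15 kb on the ppsA side (log2 −0.01). Column 3 was 1.64-fold and 1.81-fold the wild type there, and 1.52-fold and 1.41-fold when a peak of about 1 kb at the edge of the interval was left out of each block. With all columns, 1 window was past 0.3, positions 1950001 to 1960000 at 0.41, which was 0.23 without the peak, and 5 windows were with the origin window as the scale. Without column 3 there were 0, with a range of −0.11 to 0.03. By limma, 0 windows passed adjusted p under 0.05 and 122 had an unadjusted p under 0.05. Without column 2 of that library 178 passed, and without column 3 again 0 (25 unadjusted).

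**Figure D3:**
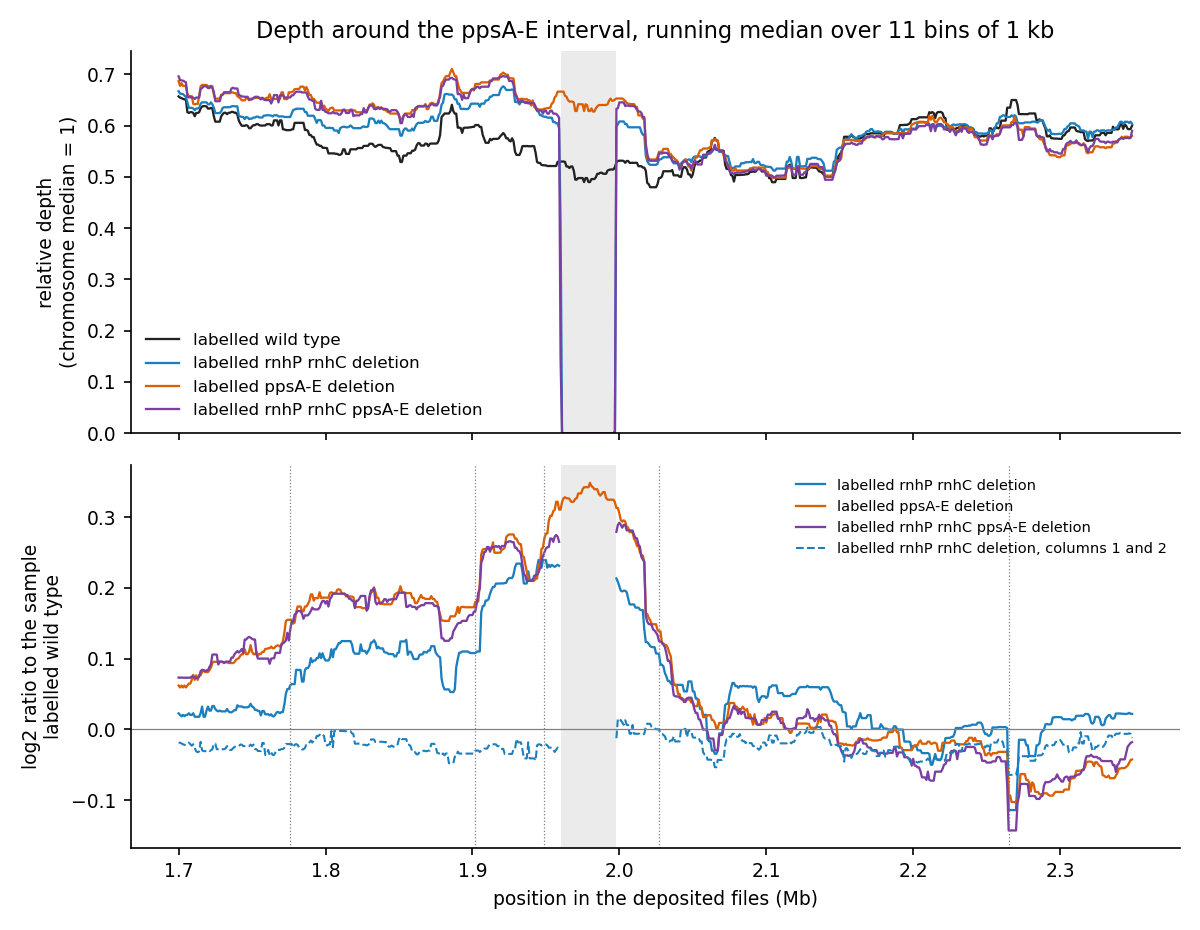
Relative depth (top) and log2 ratio to the wild type (bottom) from 1.7 to 2.35 Mb, as the running median over 11 bins of 1 kb, for the samples as labelled. The shaded area is the ppsA-E interval, the dashed line columns 1 and 2 of the sample labelled rnhP rnhC deletion, and dotted lines are 5 of the 6 steps described in the closing observations.

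Both contrasts for RNase H by label were set side by side. By the missing loci, each sets a sample without ppsA-E reads against a sample with them, and neither differs in the presence of rnhC. The sample labelled rnhP rnhC ppsA-E deletion and that labelled ppsA-E deletion, both without rnhC reads, differed by −0.04 to 0.04 in log2 depth over all 416 windows, and 100% of windows lay within 5%. Limma called 0 windows (1 at an unadjusted p under 0.05). Column 3 of the sample labelled rnhP rnhC deletion, which is outside this contrast, widens the shared spread. Without it the median SE fell from 0.0185 to 0.013, and limma still called 0 windows (5 unadjusted). A count of 0 does not show that the samples are alike. The PBSX segment differed by −0.01 ± 0.012 and the last segment by 0.01 ± 0.024. Right minus left arm was 0.12 against 0.14, a difference of −0.02, and the columns did not overlap (exact permutation test, p = 0.1; adjusted p = 0.24). Across 416 windows, which are not independent replicates, the 2 RNase H contrasts by label correlated with Pearson r = −0.40 and Spearman rho = −0.38. The sign turned to r = 0.32 and rho = 0.38 once the running median was subtracted, and to r = 0.33 without column 3 of the sample labelled rnhP rnhC ppsA-E deletion. Without column 3 of the sample labelled rnhP rnhC deletion the values were r = −0.38 and rho = −0.32. With the running median also subtracted they were r = 0.54 and rho = 0.31.

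The 2 ppsA-E contrasts by label each set a sample without rnhC reads against a sample with them, and neither differs in the presence of ppsA-E. For these contrasts the values across windows were r = 0.79 and rho = 0.76, and r = 0.28 and rho = 0.45 once the running median was subtracted. Without column 3 of the sample labelled rnhP rnhC deletion these were r = 0.94 and rho = 0.91, and r = 0.90 and rho = 0.72 with the running median subtracted. The second of these, the sample labelled rnhP rnhC ppsA-E deletion against that labelled rnhP rnhC deletion, had 139 windows higher and 128 lower by limma at adjusted p under 0.05, and 127 higher and 139 lower with the mean depth as the scale. Its PBSX segment was at 0.08 ± 0.013 and its last segment at −0.06 ± 0.021. These SDs leave out the spread of the reference, the sample labelled rnhP rnhC deletion. In the same segments the columns of that sample had SDs of 0.039 and 0.051 against the wild type. The direct contrast of both single-deletion samples, rnhP rnhC deletion against ppsA-E deletion as labelled, had 130 windows higher and 135 lower (166 and 130 with the mean depth as the scale), with the PBSX segment at −0.09 ± 0.035 and the last segment at 0.07 ± 0.051. No window was past 0.3 in either of these contrasts with all columns. Without column 3 of the sample labelled rnhP rnhC deletion, 1 window was past −0.3 in the direct contrast.

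The difference of differences, which keeps its value if the single-deletion samples trade places, had 1 window past 0.3, positions 1950001 to 1960000 at −0.44, which was −0.26 without the peak in column 3. Limma called 0 windows (47 at an unadjusted p under 0.05). Without column 3 of the sample labelled rnhP rnhC deletion the range was −0.05 to 0.12 and no window was past 0.3. Local regions were sought after subtraction of the running median. Only the targeted 38 kb at positions 1960001 to 1998000 came out, lower in 4 of the 6 contrasts. No other region of 3 or more bins was past 0.5 in any contrast. Changes of about 1 kb are too short for this search. It returned neither the empty rnhC interval of 935 bp nor the edge peaks in column 3 of the sample labelled rnhP rnhC deletion.

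Column 3 of the library labelled rnhP rnhC deletion had 2 peaks, 1 at each edge of the empty ppsA-E interval. On the ppsE side the peak ran from 1959233 to 1960229 (997 bp) at 5.12 times the depth of its flank, and on the ppsA side from 1997991 to 1998989 (999 bp) at 5.23 times. In the other 11 columns of the series these places were at 0.954 to 1.07 times their flank.

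**Figure D4:**
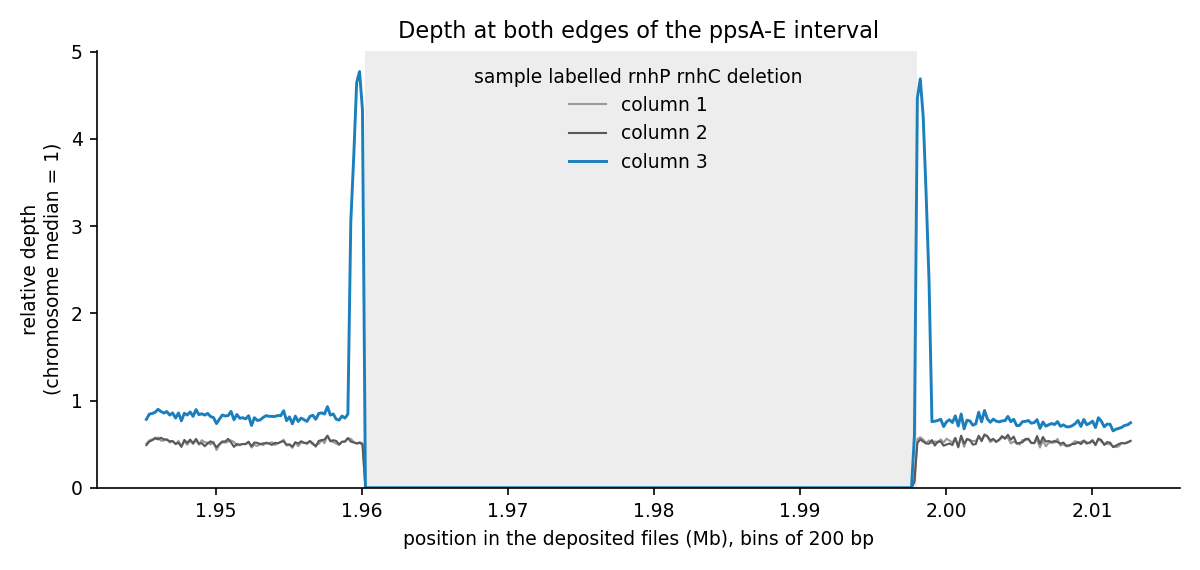
Relative depth in bins of 200 bp around the empty ppsA-E interval (shaded) in the 3 depth columns of the sample labelled rnhP rnhC deletion, against position in Mb. Column 3 has a peak of about 1 kb at each edge, 5.12 and 5.23 times its flank, and columns 1 and 2 have none.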

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

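Every test in this part was chosen only after the result it bears on had been seen. No result met the fixed rules for a single sample apart from its group or for a tested difference between backgrounds, since groups of 3 columns are not tested for outliers and limma called 0 windows for the difference of differences. The patterns below were picked because a biologist would want to follow them up.

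The missing loci went against the labels in both single-deletion samples. A single wrong label would leave exactly 1 sample in disagreement, and 2 disagreed. An exchange of the labels rnhP rnhC deletion and ppsA-E deletion may account for it: with these exchanged, 0 of 4 samples disagreed. Agreement of the wild type and of the sample labelled with all deletions was fixed in advance, because they defined the intervals. The count thus bears on the single-deletion samples alone. The chromosomal loci alone were examined, so rnhP stays open. The deposited file of the sample labelled rnhP rnhC deletion has pps in its name and that of the sample labelled ppsA-E deletion has not, which goes with the exchange, but the step at which it would have happened stays open.

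The 2 peaks at the edges of the empty interval were in column 3 of 1 sample. Cells that still held ppsA-E would put reads inside the interval, where the depth of column 3 was 0.00061% of the chromosome median (4 reads) at 100 bp or more from its edges, and 3.90e-05 of it over the whole interval. A candidate explanation is a vector that carries about 1 kb from either side of the deletion: the peaks differed in length by 2 bp, and 0 of 4130 other bins were over 2-fold. Replication starting at such a vector in the locus could also account for the broad excess around it, which fell with distance on both sides, from 1.59-fold at 10 kb to 1.03-fold at 800 kb on the ppsE side (Spearman rho −1 over 8 distances) and from 1.41-fold to 1.02-fold on the ppsA side (rho −0.905). Column 3 also had an origin to terminus ratio of 2.96, against 3.50 and 3.66 in columns 1 and 2. The locus lies near the terminus, so a flatter gradient along the whole chromosome would also fall with distance on both sides. The rank correlations therefore cannot tell replication starting at the locus from such a gradient. The sequence outside the chromosome was not analysed here, so the vector itself was not seen, and no biological explanation from the design was tested.

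The samples labelled ppsA-E deletion and rnhP rnhC ppsA-E deletion were both without rnhC reads. In each of their 6 columns, the log2 ratio to the wild type changed by −0.14 or lower between the medians on either side of 2027 kb. Wild-type depth itself changed by only 0.008 on the log2 scale between the medians around 2027 kb, so little could be predicted from it. From the fitted trend, a bias that follows local depth would predict a change of −0.000956 there. Such a trend does not account for a mean change of −0.15 and −0.17 between these medians. Absence of rnhC may account for it and stays open, as does another growth state of the culture. Right minus left arm differed by 0.19 from the wild type in the sample labelled ppsA-E deletion, but with 1 sample per genotype the spread between cultures is unknown, and genotype and any other difference between these samples cannot be told apart. Between the same medians in the sample labelled rnhP rnhC deletion, which kept rnhC reads, columns 1 and 2 gave −0.02 each. Column 3, the column with the edge peaks, gave −0.22, so a drop of this size was not limited to columns without rnhC reads.

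Other splits of the 6 columns of each contrast into 3 and 3 were also run, 10 splits in all for each, with limma on those 6 columns. These are too few for a share under 0.05. For the sample labelled ppsA-E deletion against the wild type, the real split gave 360 windows and the highest other 0, so 1 of 10 splits was as large. With the sample labelled rnhP rnhC ppsA-E deletion against the wild type these were 329 and 0, against that labelled rnhP rnhC deletion 206 and 20, and for both single-deletion samples 218 and 20, each 1 of 10. In the contrast of the sample labelled rnhP rnhC ppsA-E deletion with that labelled ppsA-E deletion the real split gave 0 and another 24, and for the sample labelled rnhP rnhC deletion against the wild type both gave 0, so 10 of 10 splits were as large in each. A real count of 0 fixes this share in advance, so it carries no information on either contrast.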

How the results depend on the processing

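Alternatives were fixed before the data were examined, except leaving out depth columns or edge peaks, the limma counts, the arm and block values and the terminus window beyond ppsA, which were chosen after seeing the data. Both loci stayed missing in 2 samples, and local regions of 3 kb or more outside the targeted interval stayed at 0, under every alternative run. With the mean depth as the scale, relative depth at ppsA-E was 0.445 in the wild type and 0.569 in the sample labelled ppsA-E deletion, and at rnhC 0.843 in the wild type and 0.864 in that labelled rnhP rnhC deletion. Scaled to the 50 kb around the locus these were 0.910, 0.976, 1.03 and 1.03, and the median over ppsA-E was 0.499 and 0.627. For the wild type, the samples labelled ppsA-E deletion and rnhP rnhC ppsA-E deletion in this order, the origin to terminus ratio was 3.51, 3.13 and 3.21 with 100 kb, 3.39, 3.04 and 3.12 with means, and 3.97, 3.54 and 3.60 from arm slopes. With the 50 kb beyond ppsA as terminus these were 3.73, 3.02 and 3.09. Right minus left arm was −0.049 with medians and −0.043 with 20 kb windows in the wild type and 0.15 with 20 kb windows in the sample labelled ppsA-E deletion.

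Windows past 0.3, in the samples labelled rnhP rnhC deletion, ppsA-E deletion and rnhP rnhC ppsA-E deletion against the wild type, were 5, 31 and 10 with the origin window as scale and 4, 9 and 7 at a threshold of 0.2. At 0.5 and with the running median subtracted the first 2 were 0. With the mean scale the last 2 were 2 and 1. For the sample labelled ppsA-E deletion, 5 kb windows gave 2 and 20 kb windows 0, and for that labelled rnhP rnhC deletion window medians gave 0. Leaving out columns gave 0 to 4 windows (rnhP rnhC deletion label), 0 to 2 (ppsA-E deletion label), 0 to 1 (rnhP rnhC ppsA-E deletion against rnhP rnhC deletion as labelled) and 0 to 1 (between single-deletion samples). The difference of differences had 5 windows at 0.2, 0 at 0.5, and 0 to 5 on leaving out columns, with 0 only without column 3 of the sample labelled rnhP rnhC deletion. Without the edge peaks it had 0, as had the sample labelled rnhP rnhC deletion against the wild type. The RNase H correlation was 0.32 with the running median subtracted and −0.54 to 0.33 on leaving out columns. The ppsA-E pair, with no running median subtracted, gave 0.79 in its place. By limma, leaving out columns gave 0 to 178 windows for the sample labelled rnhP rnhC deletion against the wild type. The ratio to the wild type beside ppsA-E with the mean scale was 0.28 and 0.27 on the ppsE side (ppsA-E and rnhP rnhC ppsA-E deletion labels), 0.35 inside and 0.31 and 0.30 on the ppsA side, and 0.28 there with the terminus as scale. Another threshold sets its count by construction; for the other changes the cause was not tested. Segment values moved by over 1 SD in 49 cases and not in 84; subtracting the running median brings them near 0 by construction, with either sign. No paired analysis was possible because each genotype is 1 sample and nothing ties the numbered columns of different samples. Counting error, 0.234% to 0.291% per window, is far below the spread between columns, so depth is not the limit.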

Other observations

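The steps, the column-wise decay and the tests on them were chosen after the data had been seen. Steps in the log2 ratio of the sample labelled ppsA-E deletion to the wild type were ranked by size on the ratio of mean depths, and the 6 listed were at 1776, 1902, 1949, 2027, 2265 and 3961 kb. As the mean of the steps in its 3 columns, the ratio was higher beyond the step by 0.06, 0.08, 0.07 and 0.05 on the log2 scale at 1776, 1902, 1949 and 3961 kb. It changed by −0.15 at 2027 kb and by −0.06 at 2265 kb. The 95th percentile of step size over 4071 bins, on the ratio of mean depths, was 0.03. In the sample labelled rnhP rnhC ppsA-E deletion the steps were 0.06, 0.10, 0.05 and 0.06, and −0.17 and −0.06. The wild-type columns that helped to choose the places are the reference for these too, so part of the likeness is built in, and no value for unchanged samples was simulated. In the sample labelled rnhP rnhC deletion the steps in order of position were 0.06 ± 0.086, 0.07 ± 0.12, 0.00 ± 0.029, −0.08 ± 0.12, −0.06 ± 0.048 and 0.00 ± 0.0077 (SD, n = 3 columns). Column 3 carried those at 1776, 1902 and 2027 kb, and the mean of columns 1 and 2 was 0.01, 0.00, 0.01, −0.02, −0.04 and 0.01 in the same order.

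The gene lists of the remaining segments were as follows. All 57 SPbeta prophage genes and 33 of 34 genes of the skin element lie by gene order between the ppsA-E interval and rnhC. There the sample labelled ppsA-E deletion was at −0.05 ± 0.012 against the wild type and that labelled rnhP rnhC ppsA-E deletion at −0.04 ± 0.0083. The 12 listed genes of the mobile element ICEBs1 lie between the rRNA gaps 4 and 5, where these samples were at 0.03 ± 0.036 and 0.03 ± 0.039. Of 86 tRNA genes, 22 lie before the end of gap 4 and 21 between rnhC and gap 7, and the latter segment was at −0.10 ± 0.0096 and −0.09 ± 0.014. Of 23 competence genes, 13 lie between the ppsA-E interval and rnhC, as do 33 of 87 sporulation genes, and 12 of 36 replication and repair genes lie in the PBSX segment. No local region past 0.5 was found in these segments outside the targeted interval, but the running median over 100 bins either side removes a change wider than about 100 bins, so the search does not cover a long prophage as a whole.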
